A study of Mus musculus with 35 samples.

How the data were processed

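Single-cell CEL-seq counts of mouse small-intestinal cells were analysed from deposited tables with 1 column per well and 1 row per gene. The labels list 35 library entries. Plates of 1 passage or sort were joined into 1 replicate, which gave 2 whole organoid, 2 Reg4-positive organoid, 1 Lgr5-positive organoid, 2 Lgr5-EGFP ex vivo and 5 YFP ex vivo replicates. These tables held 1680 wells. For each Reg4-positive replicate the labels name samples I to III, while the tables used here hold 1 plate of replicate 1 and 2 plates of replicate 2, and which labelled samples these are is not given in the sources used here. The table of the Lgr5-positive organoid library was matched by the table's name alone, the other entries with Lgr5 in their labels having columns named for them, so values of this library rest on that match. Another 2 tables of 96 wells each could be matched to no library entry from their names, so they entered no comparison. Organoid replicates were passages of 1 culture per genotype and ex vivo replicates were plates. For ex vivo plates the labels do not say whether the animals differed, so p-values measured only the spread between passages or plates.

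The deposited values are estimated counts of transcripts, made by the authors from the numbers of distinct 4-base molecular barcodes per gene and well. Per the submitters' processing notes, reads were aligned with BWA 0.6.2-r126 to mm10 (GRCm38). The counting, filters and gene annotation used by the authors are not given in the sources used here. The values themselves showed the unit: of 4461615 nonzero values 4461589 became whole barcode numbers (tolerance 1e-06) when a correction for barcodes drawn more than once, with 256 possible barcodes, was inverted. The other 26 were saturated at 1597.01. With 256 barcodes the correction is steep for abundant transcripts, so levels such as those of defensins in single wells are imprecise. No value had been scaled between wells.

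Each table held 23630 rows, of which 23538 were genes and 92 were spike-in RNAs. Spike-ins and the dsRed reporter entry were left out of totals and tests. Values were rounded to whole numbers per gene and well, which moved no value by more than 0.495, wells with fewer than 1500 counts of genes were left out, and the rest were summed per replicate. No kept well of 1209 was identical to another. Counts per replicate ran from 293702 to 2870987 over all wells and from 287001 to 2860636 over the kept wells. Intervals and limits of a count of 0 (3 counts) cover counting error only, and a fold against such a limit is the lower of the ratios from summed counts and from mean levels.

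Genes were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg false discovery rate 0.05) in R 4.3.3. The 3 organoid groups shared 1 fit, in which the single Lgr5-positive replicate was assumed to vary like the others, and the ex vivo groups had their own. Standard errors were the log2 fold change divided by the root of the F statistic. CPM are counts relative to the TMM-scaled library total. The comparisons, tests, 15 gene lists, cell type markers, rule for named genes and most alternatives were fixed before the data were examined. The lists covered stem, enteroendocrine, gut hormone, Paneth, goblet, tuft, enterocyte, secretory progenitor, cell cycle, immediate early and heat shock, MHC class II, immune, stromal, embryonic stem cell and fibroblast genes. They were tested with camera (limma 3.58.1, at least 3 tested members) with a preset correlation of 0.01 and again with an estimated one. Named genes were Reg4 and Lgr5, then up to 10 increases and 10 decreases with the largest fitted change among called genes of at least 50 CPM in the higher group and 1 direction in every pair of replicates, then up to 4 members of each list with the highest mean level. The text gives values for part of the genes that the rule takes, and 1 of them is not reported here. Coordinates came from GENCODE release M21 on GRCm38.

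For cell classes, wells were scaled to 10000 counts and logged, and 2000 variable genes, 20 principal components, 10 neighbours and Leiden clustering at resolution 1 were used (scanpy 1.11.5, igraph 0.11.9, Python 3.11.15), separately for organoid and ex vivo wells. A cluster was named for a class when at least 3 of its markers were raised at least 2-fold (pseudocount 1) and counted in at least 25% of wells. The class also had to have more markers among the 10 leading genes than any other class. This naming rule replaced a first version with a pseudocount of 0.05 after the clusters had been seen. Both gave the same enteroendocrine-like shares in organoid wells and the same enterocyte-like shares in ex vivo wells. The shares of the other classes, and of enterocyte-like wells in organoids, were not compared between the rules. Shares were compared with two-sided exact permutation tests of replicates (scipy 1.17.1), and exact binomial intervals at 95% were computed per replicate. Cells had been sorted singly into wells, no doublet caller was run, and 3 wells above 100000 counts were left out as an alternative.

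The gene test was tested on simulated counts with 200 changed genes in 8 draws per comparison. With the spread varying gene by gene, 8.92% of calls were false for Reg4-positive against whole organoid (9985 genes), 10.3% for Lgr5-positive organoid against whole organoid (9988 genes) and 7.70% for YFP against Lgr5-EGFP (8634 genes), above the nominal rate. Genes changed 4-fold were recovered at 64.2%, 37.1% and 97.9%, and genes changed 2-fold at 5.22%, 2.99% and 65.9%. The changed genes were drawn only from those with an expected count of at least 5 in the smallest library. Recovery among genes of lower counts was not measured. A goblet list raised 4-fold was called by camera in 8 of 8 draws with the preset correlation, and with an estimated one in 5, 1 and 8 draws. With no change the preset correlation called 0.625, 0.5 and 1.125 lists on average. Genes were drawn independently of each other in these simulations. In the Reg4-positive comparison the correlation estimated within lists ran from -0.00767 (secretory progenitor) to 0.854 (goblet). The simulated rates therefore leave out false list calls that come from correlated genes.

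Alternatives were scaling by DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, well minimums of 500 and 3000 counts, wells thinned to 1500 counts, 1 fit over all 5 groups, the replicate number as a block, plates as units, wells 49 to 96 of the last plate of whole organoid replicate 2 left out, resolutions of 0.5 and 2, and each replicate left out. The sources say that wells 49 to 96 of a sample 4 hold unrelated cells. This was read as YFP replicate 4, whose table ends at well 48, but the wording also allows plate IV of whole organoid replicate 2, whose wells 49 to 96 were kept and left out only in that alternative. Alternatives added after seeing the data were wells above 100000 counts left out, whole barcode numbers in place of corrected counts, and the first naming rule. Figures were drawn with matplotlib 3.10.9.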

Results

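Polyadenylated RNA of single mouse small-intestinal cells was counted by CEL-seq, in which each cell is lysed in its own well, its transcripts receive a well barcode and a 4-base molecular barcode, and distinct molecular barcodes are counted per gene. Part of the cells came from organoids, epithelial structures that crypts form in gel culture and that hold stem cells and their differentiated descendants. Cells were taken without a reporter sort from organoids of a wild-type mouse (whole organoid, 2 passages), and by fluorescence sorting from organoids of a Reg4-dsRed knock-in mouse (Reg4-positive, 2 passages) and of an Lgr5-GFP-DTR mouse (Lgr5-positive, 1 replicate). The other cells were sorted directly from intestine, either as Lgr5-EGFP-positive cells (2 plates) or as YFP-positive cells 5 days after Lgr5-Cre labelling (5 plates). Lgr5 is a receptor of crypt base stem cells, so YFP marks stem cells labelled 5 days earlier together with their descendants. Every organoid group came from 1 mouse of its own genotype, so the sort could not be told apart from the mouse and the culture, and p-values measured only the spread between passages or between plates.

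Total counts were 2870987 and 1641473 in the whole organoid replicates, 500618 and 1109577 in the Reg4-positive replicates, 908578 in the Lgr5-positive organoid replicate, and 937521 and 1212923 in the Lgr5-EGFP plates. They lay between 293702 and 818192 in the 5 YFP plates. Spike-in RNA made up 8.21% and 12.2% of the counts in whole organoid and 3.36% and 5.87% in Reg4-positive replicates. In the Lgr5-positive organoid replicate it made up 4.70%, so the organoid groups differed in this share too. Plate I of Reg4-positive replicate 2 had 26.8% spike-in RNA, and 9 of its 96 wells were kept. The labels name samples I to III for each Reg4-positive replicate, while the tables used here hold 1 plate of replicate 1 and 2 plates of replicate 2, so totals and shares cover these plates alone. Wells with at least 1500 counts of genes were kept. This left 276 and 209 whole organoid wells, 75 and 81 Reg4-positive wells, 74 Lgr5-positive organoid wells, 75 and 84 Lgr5-EGFP wells, and from 35 to 80 wells per YFP plate, 1209 in all. The median count per kept well was 7982 and 4608 in whole organoid, 5148 and 5695 in Reg4-positive, 11905.5 in Lgr5-positive organoid, 9543 and 13131.5 in Lgr5-EGFP, and 5576 to 7739.5 in YFP wells. In Reg4-positive replicate 2, 3 wells with 162627, 179260 and 188892 counts held 49.3% of the kept counts, and all 3 lay in the cluster called stem-like, so that part of the summed library came from stem-like wells.

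The cells were grouped by clustering, and a cluster was called X-like when fixed markers of that cell type led it. Enterocyte-like wells, from the absorptive lineage, made up 142 of 276 wells (51.4%) in whole organoid replicate 1 and 12 of 209 (5.74%) in replicate 2. Part of this gap depends on the naming rule. Unnamed clusters with 9, 6 and 4 raised enterocyte markers, none of them leading, held 14, 47 and 26 wells of replicate 2. The same clusters held 4, 0 and 29 wells of replicate 1. Fabp1, an enterocyte marker, was counted in 93.8% of replicate 1 and 73.7% of replicate 2 wells. Paneth-like wells, from the antimicrobial cells of the crypt base, were 0 of 276 and 3 of 209 in whole organoid, where 0 of 276 allows a share of up to 1.09%, and 10 of 75 (13.3%) and 16 of 81 (19.8%) among Reg4-positive wells. Enteroendocrine-like wells, from the hormone-secreting lineage, were 21 of 276 (7.61%) and 3 of 209 (1.44%) in whole organoid, 7 of 75 (9.33%) and 49 of 81 (60.5%) in the Reg4-positive replicates, and 1 of 74 in the Lgr5-positive organoid replicate. Exact 95% binomial intervals, which cover counting error only, were 3.84% to 18.3% and 49.0% to 71.2% for the Reg4-positive shares. A further cluster, led by 5 goblet and 5 Paneth markers and therefore left unnamed, held 49 of 75 wells (65.3%) of Reg4-positive replicate 1 and 6 of 81 (7.41%) of replicate 2. In the Lgr5-positive organoid replicate, 68 of 74 wells fell into 1 stem-like cluster, which held 80 wells in all and so was mostly 1 library.

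**Figure D1:**
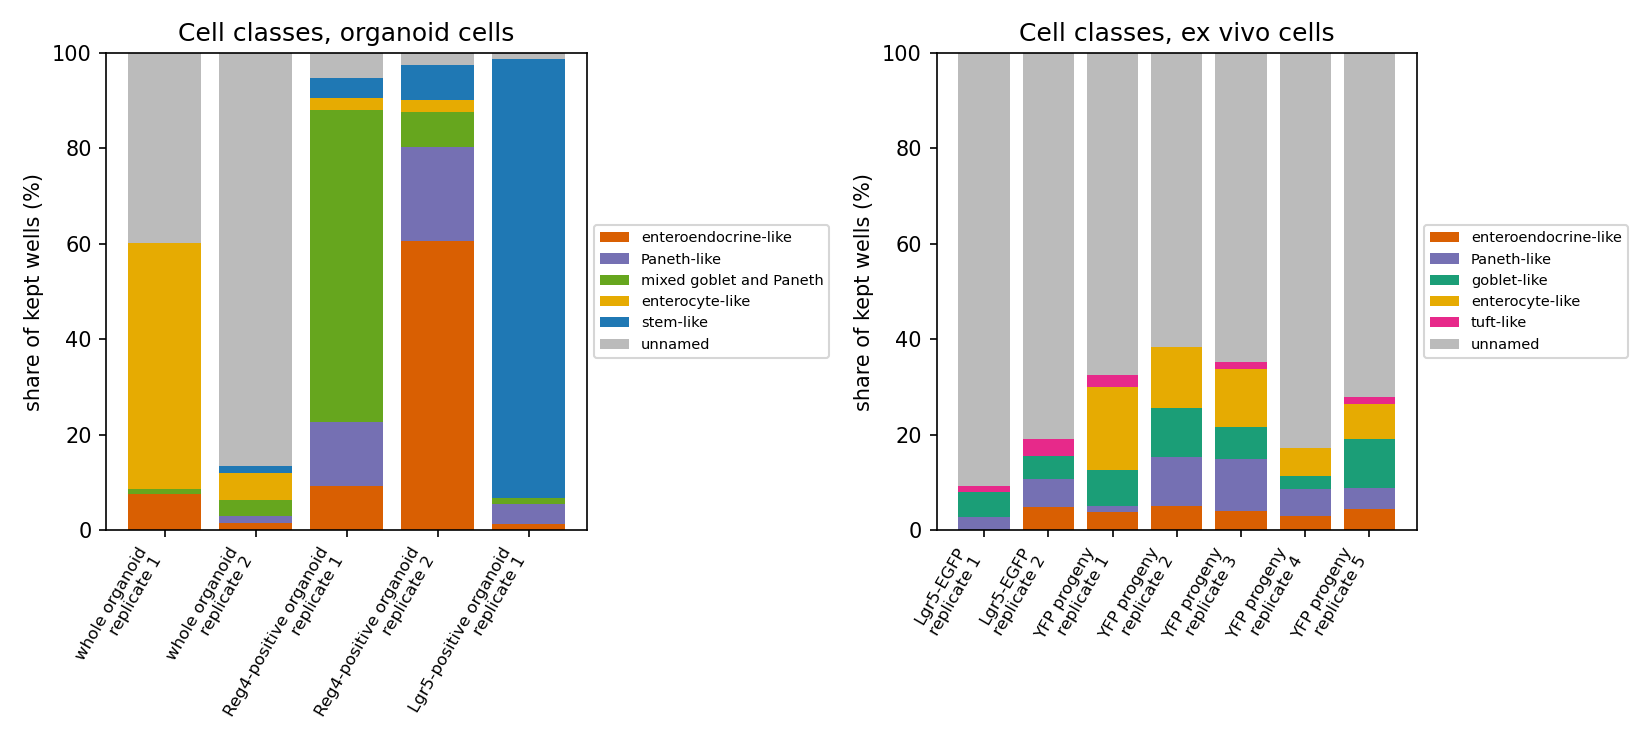
Share of kept wells (vertical axis, %) in each named cell class, one stacked bar per replicate, for organoid cells on the left and ex vivo cells on the right; the cluster with both goblet and Paneth markers is drawn apart from the other unnamed wells. Enteroendocrine-like wells were 9.33% of Reg4-positive replicate 1 and 60.5% of replicate 2, and enterocyte-like wells appeared in all 5 YFP plates and in neither Lgr5-EGFP plate.

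The Reg4 sort asks which cell types express Reg4, a gene of secretory cells of the gut. Of 22 Paneth genes tested, 16 rose in Reg4-positive against whole organoid libraries, of 9 gut hormones 4 rose, and of 22 enterocyte genes 18 fell. None of these lists passed camera with an estimated correlation (adjusted p = 0.291 for each with an estimated correlation). Among all 10522 genes tested, 252 rose and 428 fell at a false discovery rate of 0.05 (edgeR quasi-likelihood test, 2 against 2 replicates). Reg4 itself (chromosome 3, 98222156 to 98236748, GRCm38) stood at 4925 ± 3368 CPM (counts per library scaled to a common total) in Reg4-positive and 775 ± 950 in whole organoid libraries (SD, n = 2 each). Its log2 fold change of 2.67 (SE 1.04) did not pass (edgeR adjusted p = 0.185). Per library Reg4 stood at 2544 and 7307 CPM in the Reg4-positive and at 1447 and 103 in the whole organoid replicates. Lgr5 (chromosome 10, 115450311 to 115587780) stood at 135 ± 76.6 against 45.1 ± 22.7 CPM and did not pass either (log2 fold change 1.56, SE 0.51, edgeR adjusted p = 0.116). Reg4 passed with each well thinned to 1500 counts and without whole organoid replicate 1, and Lgr5 passed without Reg4-positive replicate 2 and without whole organoid replicate 2. Leaving out 1 of 2 replicates takes away the spread between them, so passes of that kind in this comparison are weak support.

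Among the Paneth genes, the defensin gene Gm14851 (chromosome 8, 21095074 to 21096050) rose from 3.06 ± 1.08 to 6817 ± 5178 CPM (log2 fold change 11.13, SE 0.89, edgeR adjusted p = 0.0103). The defensin Defa24 went from 1186 ± 1459 to 43676 ± 32791 CPM (log2 fold change 5.20, SE 1.21, edgeR adjusted p = 0.0437). Mptx1 and Mptx2, genes of mucosal pentraxins, rose by log2 9.90 (SE 1.38) and 8.61 (SE 1.43), and Itln1, a carbohydrate-binding lectin, rose by log2 5.01 (SE 1.09). Lyz1, the lysozyme of Paneth cells, stood at 14049 ± 11083 against 417 ± 557 CPM and did not pass (edgeR adjusted p = 0.0768), but passed with thinned wells and when Reg4-positive replicate 2 or either whole organoid replicate was left out. Defensin genes lie together on chromosome 8 as closely related copies, so the counts of Defa24, Gm14851 and AY761184 as single genes are uncertain. Adjusted over the list alone, 21 of the 22 Paneth genes rose. The list passed camera's test with a preset correlation (adjusted p = 1.74e-24) but not with an estimated one (adjusted p = 0.291 with an estimated correlation). Without Reg4-positive replicate 1 the calls on Defa24, Itln1 and AY761184 ended, and without the 3 wells above 100000 counts those on Defa24 and Itln1 ended. Both also ended without wells 49 to 96 of plate IV of whole organoid replicate 2, and that on Defa24 with a well minimum of 3000 counts.

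The gut hormones that rose were 4 of 9, and of 21 enteroendocrine genes 3 rose. Ghrl (chromosome 6, 113716119 to 113719880), which encodes ghrelin, rose from 2.04 ± 1.99 to 804 ± 746 CPM (log2 fold change 8.39, SE 0.99, edgeR adjusted p = 0.0108). Cck, which encodes cholecystokinin, rose from 7.47 ± 10.6 to 610 ± 41.6 (log2 fold change 6.19, SE 0.94, edgeR adjusted p = 0.0153), a call that DESeq2 did not make. The other hormones that rose, named after their values were seen, were Sct (secretin) and Gcg (glucagon), the latter with 202 counts in Reg4-positive replicate 2 and 0 in replicate 1. Tac1, a tachykinin precursor, stood at 1331 ± 1022 against 85.7 ± 120 CPM and did not pass (edgeR adjusted p = 0.156). The enteroendocrine genes that rose were the granule proteins Scg2 and Scg5 and the prohormone convertase Pcsk1, also named after their values were seen. Adjusted over the list alone, 7 hormone and 4 enteroendocrine genes rose. The granins Chgb (7411 ± 6520 against 915 ± 1292 CPM) and Chga (2135 ± 2236 against 211 ± 298) did not pass (edgeR adjusted p = 0.382 and 0.311). With thinned wells and without whole organoid replicate 1 Tac1, Chgb and Chga passed, and Tac1 and Chga also without replicate 2. In whole organoid, Chgb stood at 1828 CPM in replicate 1 and 1.91 in replicate 2. It was counted in 77.2% of the replicate 1 wells, against 1.44% of replicate 2 wells. Both lists passed camera with a preset correlation (adjusted p = 2.82e-08 for hormones and 6.73e-09 for enteroendocrine genes). Neither passed when the correlation was estimated (adjusted p = 0.291 and 0.388 with an estimated correlation).

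Of 16 goblet genes tested, 6 rose, among them Muc2, the main secreted mucin, from 30.1 ± 32.2 to 1614 ± 1736 CPM (log2 fold change 5.78, SE 1.19, edgeR adjusted p = 0.0302). Spink4, Tff3 and Fcgbp stood at 6459 ± 3932, 5333 ± 3629 and 743 ± 663 CPM in Reg4-positive libraries, above 736 ± 704, 922 ± 860 and 341 ± 241 in whole organoid, without passing. All of these passed without whole organoid replicate 2, and Spink4 and Tff3 also without Reg4-positive replicate 2 and with thinned wells. Spink4 passed without whole organoid replicate 1 as well. Adjusted over the list alone, 11 goblet genes rose and 1, Zg16, fell. Of 7 secretory progenitor genes 3 rose, and these were Cbfa2t3 (log2 fold change 2.42, SE 0.47) and the transcription factors Atoh1 and Gfi1, the last pair named after their values were seen. For the list alone the count was 5. Among 16 stem cell genes, Igfbp4 rose, and 5 rose when adjusted over the list alone. The goblet, secretory progenitor and stem lists passed camera with a preset correlation (adjusted p = 2.82e-08, 0.000728 and 6.10e-05) and not with an estimated one (adjusted p = 0.388, 0.291 and 0.380 with an estimated correlation). The calls on Muc2, Cbfa2t3 and Gas6 ended without Reg4-positive replicate 1, and that on Gas6 also without the 3 wells above 100000 counts. Gas6, a secreted growth factor ligand, and the microRNA gene Mir692-1 had no count in whole organoid and were at least 53.3-fold and 77.0-fold higher in Reg4-positive libraries, taking 3 counts over the group as the limit of a count of 0 and the lower of the ratios from summed counts and from mean levels.

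Among the 18 enterocyte genes that fell, Apoa4 (chromosome 9, 46240696 to 46243459), an apolipoprotein of fat absorption, fell from 2568 ± 718 to 108 ± 5.79 CPM (log2 fold change -4.57, SE 0.43, edgeR adjusted p = 0.0103), and Reg1 fell from 6523 ± 4001 to 406 ± 0.0254 (log2 fold change -4.01, SE 0.55, edgeR adjusted p = 0.0122). Fabp1, the liver fatty acid binding protein, stood at 631 ± 19.1 against 2565 ± 1686 CPM and did not pass (edgeR adjusted p = 0.0567), but passed, among other settings, by DESeq2, with thinned wells and without whole organoid replicate 2. Adjusted over the list alone, 21 enterocyte genes fell. The list passed camera with a preset correlation (adjusted p = 6.42e-31) and not with an estimated one (adjusted p = 0.291 with an estimated correlation). Outside the list, the detoxification gene Cyp2c29 fell by 5.71 on the log2 scale (SE 0.96) and the growth factor Areg fell from 506 counts in whole organoid to 3 in Reg4-positive libraries, a ratio of 62.3 with a counting interval of 21.2 to 303. The calls on Cyp2c29 and Areg ended without Reg4-positive replicate 1, that on Cyp2c29 also without the 3 wells above 100000 counts, and DESeq2 did not call Cyp2c29. The galectin gene Lgals3 and the transporter gene Slc5a4b had no count in Reg4-positive libraries and were at least 45.9-fold and 47.7-fold lower there.

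Several fixed lists showed no called member. By edgeR, none of 20 cell cycle, 17 immediate early and heat shock or 6 tuft genes changed. Over the tuft list alone 1 gene fell. Camera called the immediate early and heat shock list lower with a preset correlation (adjusted p = 0.0142) but not with an estimated one (adjusted p = 0.558 with an estimated correlation), and it did not call the cell cycle (adjusted p = 0.807), tuft (adjusted p = 0.0815) or fibroblast (adjusted p = 0.540) lists. The immediate early list lost its call without Reg4-positive replicate 2, without whole organoid replicate 2, with each well thinned to 1500 counts and with plates as units. The tuft list was called lower without whole organoid replicate 2, without the 3 wells above 100000 counts and without a filter on low counts. The cell cycle list was called lower without the 3 wells above 100000 counts and higher without Reg4-positive replicate 1. In the fibroblast list Vim, an intermediate filament gene, rose from 10.0 ± 9.67 to 187 ± 185 CPM (edgeR adjusted p = 0.0327), a call that ended without Reg4-positive replicate 2 and without its 3 wells above 100000 counts. Fewer than 3 members of the immune, stromal, embryonic stem cell and MHC class II lists passed the count filter in organoids, so these lists had no test there.

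The enteroendocrine-like share was 34.9% ± 36.2 in Reg4-positive and 4.52% ± 4.37 in whole organoid libraries (SD, n = 2 each). The difference of 30.4 percentage points had a two-sided exact permutation p = 0.333, the smallest that 2 against 2 replicates allow, and it was 4.81 points without Reg4-positive replicate 2 and 56.0 points without replicate 1. The sort for Reg4 can itself set this share. Of the Reg4-positive enteroendocrine-like wells, 5 and 37 lay in a cluster led by Cck, Chgb and Tac1 and 2 and 12 in one led by Afp and Reg4, while a cluster led by Neurog3 held 6 and 3 whole organoid wells and no Reg4-positive well. Without Reg4-positive replicate 1 the edgeR test called 209 genes, and without the 3 wells above 100000 counts, an exclusion chosen after seeing the data, it called 472, of which 224 rose and 248 fell. It called 1716 genes without a filter on low counts, 1910 in 1 fit over all 5 groups and 1128 with plates as units. The last setting takes plates of 1 passage as replicates, so its p-values mix the spread between such plates with that between passages.

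**Figure D2:**
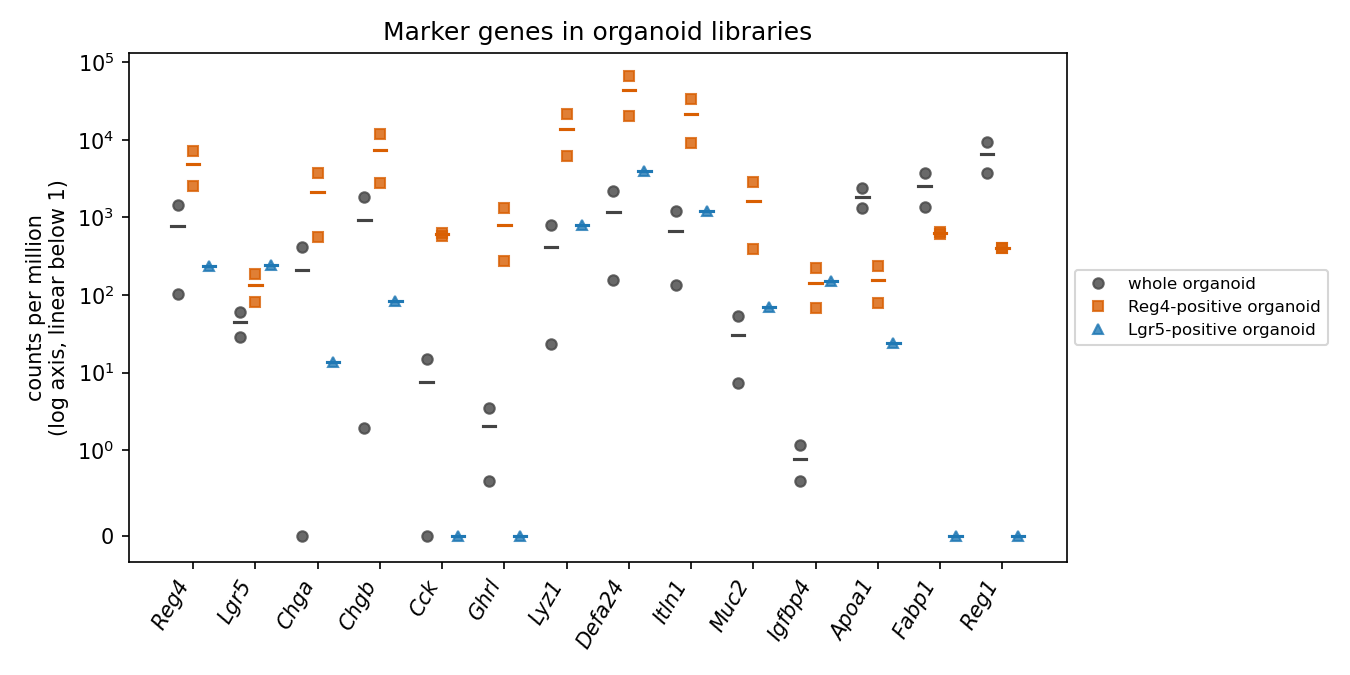
Level in CPM (vertical axis, logarithmic above 1 and linear below) of marker genes in organoid libraries; each symbol is 1 replicate and each dash a group mean. Fabp1 and Reg1 had no count in the Lgr5-positive organoid library, and Chgb stood at 1828 and 1.91 CPM in the 2 whole organoid replicates.

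The Lgr5-positive organoid library was set against the whole organoid libraries to describe stem cells in culture. Its table was matched to the labels by its own name, since its columns carry no library name. Where a whole organoid replicate was left out, 1 library was set against 1. The spread then came from the Reg4-positive pair alone, so such settings are weak support for any gene or list below. Of 16 stem genes 4 rose, and of 22 enterocyte genes 16 fell. Neither list passed camera with an estimated correlation (adjusted p = 0.355 for each with an estimated correlation). Of 10522 genes 69 rose and 313 fell (edgeR quasi-likelihood test, 1 against 2 replicates, the single replicate being assumed to vary like the other organoid groups, so that this library has no replicate check of its own). Lgr5 stood at 244 CPM against 45.1 ± 22.7 (SD, n = 2) and did not pass (log2 fold change 2.45, SE 0.57, edgeR adjusted p = 0.0584), but passed, among other settings, by DESeq2, with thinned wells and when any 1 of the other organoid libraries was left out. Reg4 stood at 234 against 775 ± 950 CPM and did not pass (edgeR adjusted p = 0.484), except without whole organoid replicate 2 or without a filter on low counts.

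Of the stem list, Igfbp4 (chromosome 11, 99041244 to 99054392), which encodes a binding protein of insulin-like growth factors, stood at 152 against 0.893 ± 0.362 CPM (log2 fold change 7.19, SE 0.82, edgeR adjusted p = 0.0112). Ascl2, a transcription factor of crypt stem cells, rose by log2 3.14 (SE 0.57, edgeR adjusted p = 0.0306), and Cdca7 rose by log2 2.40 (SE 0.36, edgeR adjusted p = 0.0191). Rnf43, a negative regulator of Wnt receptors, was the other stem gene that rose and was named after its values were seen. Clca4, Smoc2 and Slc12a2 stood at 812, 406 and 664 CPM against 298 ± 19.0, 159 ± 23.8 and 309 ± 19.5, without passing, though Clca4 and Smoc2 passed by DESeq2, with thinned wells and without Reg4-positive replicate 2. Adjusted over the list alone, 13 stem genes rose. Outside the list Gkn3 rose by log2 3.73 (SE 0.56), and Retnlb, a resistin-like secreted protein, had no count in whole organoid and 254 counts in the Lgr5-positive library, at least 341-fold more. The call on Retnlb was not made by DESeq2. Camera called the stem list with a preset correlation (adjusted p = 8.67e-13) and not with an estimated one (adjusted p = 0.355 with an estimated correlation). The calls on Ascl2, Cdca7 and Gkn3 ended without the 3 wells above 100000 counts in Reg4-positive replicate 2, which entered the shared estimate of the spread.

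Of the enterocyte list, Reg1, Fabp1, Gsta1 and Alpi, the last encoding intestinal alkaline phosphatase, had no count in the Lgr5-positive library. They were at least 2259.9-fold, 889-fold, 790.3-fold and 609-fold lower than in whole organoid, where they stood at 6523 ± 4001, 2565 ± 1686, 2281 ± 1478 and 1757 ± 279 CPM. Apoa4 fell by 7.67 on the log2 scale (SE 0.70, edgeR adjusted p = 0.0074). For the list alone 20 fell. Of 17 immediate early and heat shock genes 4 fell, namely Fos (log2 fold change -5.37, SE 1.09, edgeR adjusted p = 0.0393) and, named after their values were seen, Junb, Ier3 and Zfp36. The call on Fos ended without the 3 wells above 100000 counts and with a well minimum of 3000 counts. For that list alone 13 fell. Camera called the enterocyte list and the immediate early and heat shock list lower with a preset correlation (adjusted p = 1.79e-38 and 1.99e-08) and not with an estimated one (adjusted p = 0.355 and 0.524 with an estimated correlation).

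Of 22 Paneth genes 1 rose, Gm14851, from 3.06 ± 1.08 to 338 CPM, and over the list alone 8 rose and 1 fell, Nupr1, named after its values were seen. By edgeR, none of 20 cell cycle, 21 enteroendocrine, 9 gut hormone, 16 goblet, 6 tuft, 7 secretory progenitor or 4 fibroblast genes changed. Over the cell cycle list alone 2 rose, Top2a, which stood at 408 against 113 ± 31.0 CPM, and Gins2, the latter named after its values were seen. Camera called the Paneth and cell cycle lists higher and the tuft list lower with a preset correlation (adjusted p = 2.79e-07, 2.76e-05 and 0.0102) and not with an estimated one (adjusted p = 0.657 for each with an estimated correlation). It did not call the enteroendocrine (adjusted p = 0.0520), hormone (adjusted p = 0.462), goblet (adjusted p = 0.929), secretory progenitor (adjusted p = 0.743) or fibroblast (adjusted p = 0.664) lists. Without whole organoid replicate 1 the goblet list was called lower and without replicate 2 higher. The hormone list was called lower without whole organoid replicate 2, and the enteroendocrine list without that library or either Reg4-positive replicate, and also without a filter on low counts, with a well minimum of 500 counts, with plates as units, without wells 49 to 96 of plate IV of whole organoid replicate 2 and with whole barcode numbers. Top2a passed by DESeq2 and when any of these 3 libraries was left out. Likewise Chga and Chgb, which stood at 13.5 and 84.7 CPM against 211 ± 298 and 915 ± 1292, were called higher without whole organoid replicate 1 and lower without replicate 2. The goblet list here, and the fibroblast list in the Reg4-positive comparison, had a median and a mean below 0 beside a positive test direction, and the secretory progenitor list here had a median below 0. The number of called genes was 143 without the 3 wells above 100000 counts, 203 with each well thinned to 1500 counts, 247 with plates as units, 1372 without a filter on low counts and 1738 in 1 fit over all 5 groups. It was 931 without Reg4-positive replicate 2 and 837 without whole organoid replicate 2.

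The ex vivo cells address what Lgr5-positive cells give rise to within 5 days. Of 22 enterocyte genes 20 rose in the YFP against the Lgr5-EGFP plates and 2, the antimicrobial lectins Reg3b and Reg3g, fell. Of 7 MHC class II genes 6 fell, and of 16 stem genes 7 fell. None of these lists passed camera with an estimated correlation (adjusted p = 0.310, 0.170 and 0.507 with an estimated correlation). Of 9065 genes tested 1332 rose and 998 fell (edgeR quasi-likelihood test, 5 against 2 plates). Lgr5 fell from 152 and 115 CPM in the Lgr5-EGFP plates to 73.8 ± 19.8 (SD, n = 5) CPM (log2 fold change -0.91, SE 0.20, edgeR adjusted p = 0.00434), a call that ended without Lgr5-EGFP replicate 1. Reg4 stood at 478 ± 135 against 406 ± 381 and did not pass (edgeR adjusted p = 0.720), except without Lgr5-EGFP replicate 1.

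Beside these changes the plates of the 2 groups differed in their whole libraries. Spike-in RNA made up 0.925% and 0.948% of the counts in the Lgr5-EGFP plates and 6.81% to 8.84% in the YFP plates. Malat1, a nuclear RNA, stood at 709 and 542 CPM in the Lgr5-EGFP plates and at 140.2 to 235 in the YFP plates. Wells without a named class mostly clustered by group. A pair of unnamed clusters held 58 and 77 wells, all from Lgr5-EGFP plates, and 4 others held 75, 54, 57 and 43 wells, of which 1 was from an Lgr5-EGFP plate. Each plate was of 1 group, so a difference between plates could not be told apart from the sort.

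Several enterocyte genes lacked any count in the Lgr5-EGFP plates. Rbp2, Alpi and Lct, the last encoding lactase, were at least 142-fold, 116-fold and 57.8-fold higher in YFP plates, where they stood at 163 ± 122, 134 ± 73.2 and 66.3 ± 43.2 CPM (SD, n = 5). Apoa1 had 1 count in the Lgr5-EGFP and 2018 in the YFP plates, a ratio of 1865 with a counting interval of 334 to 73710.5. Fabp2 rose from 96.0 ± 18.1 to 1216 ± 542 CPM (log2 fold change 3.67, SE 0.45, edgeR adjusted p = 7.84e-05). The enterocyte list members that fell, Reg3b and Reg3g, are antimicrobial lectins rather than absorptive genes. Reg3b (chromosome 6, 78370657 to 78373466) fell from 4525 ± 399 to 436 ± 150 CPM (log2 fold change -3.39, SE 0.23, edgeR adjusted p = 2.89e-06) and Reg3g from 4121 ± 309 to 469 ± 141 (log2 fold change -3.14, SE 0.22, edgeR adjusted p = 2.89e-06), and these are neighbouring paralogs, so the split of counts between them is uncertain. The counts over the list alone were the same, 20 and 2. Camera called the list higher with a preset correlation (adjusted p = 1.14e-12) and not with an estimated one (adjusted p = 0.310 with an estimated correlation).

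Enterocyte-like wells made up 17.5%, 12.8%, 12.2%, 5.71% and 7.35% of the 5 YFP plates, a mean of 11.1% ± 4.69 (SD, n = 5), and 0 of 75 and 0 of 84 wells of the Lgr5-EGFP plates, which allow shares of up to 4.00% and 3.57%. The two-sided exact permutation p was 0.0952, the smallest that 2 against 5 plates allow. With each well thinned to 1500 counts, which left out no kept well, the mean share was 5.26% (two-sided exact permutation p = 0.286), and it was 5.18% when the wells were clustered without YFP replicate 5. The median well of each Lgr5-EGFP plate was deeper than that of any YFP plate.

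The stem genes that fell did so by small amounts beside the enterocyte changes. Besides Lgr5 they were Igfbp4, Rnf43, Mex3a, Soat1, Prom1 and Rgmb, named after their values were seen. Smoc2 and Clca4 stood at 241 ± 48.2 and 1129 ± 129 CPM in YFP and at 238 ± 25.4 and 966 ± 217 in Lgr5-EGFP plates, without passing (edgeR adjusted p = 0.993 and 0.350). Over the stem list alone the count was again 7. Of 7 MHC class II genes, which present peptides to helper T cells, 6 fell: H2-Eb1 went from 461 ± 41.4 to 176 ± 45.3 CPM (log2 fold change -1.36, SE 0.20, edgeR adjusted p = 0.000239), H2-Aa fell by 1.25 on the log2 scale (SE 0.22) and H2-Ab1 by 1.09 (SE 0.19). Their invariant chain Cd74 stood at 233 ± 94.5 against 299 ± 65.7 and did not pass (edgeR adjusted p = 0.452). For this list alone 6 fell. Of 6 secretory progenitor genes 2 fell, Sox4 by 1.85 (SE 0.17) and Hes6 by 0.59 (SE 0.17) on the log2 scale, and over the list alone 3 fell and 1 rose. The call on Hes6 was not made by DESeq2 and ended without Lgr5-EGFP replicate 2, and the list lost its call without YFP replicate 4. With a preset correlation camera called the stem, MHC class II and secretory progenitor lists lower (adjusted p = 0.0107, 1.11e-07 and 0.0276), and with an estimated one none of them (adjusted p = 0.507, 0.170 and 0.310 with an estimated correlation).

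Some genes of secretory cell types were higher in YFP plates. Of 22 Paneth genes 10 rose and 2, Defa20 and Pla2g2a, fell, the latter pair named after their values were seen. Defa24 rose from 3005 ± 1113 to 11115 ± 5734 CPM (log2 fold change 1.89, SE 0.49, edgeR adjusted p = 0.0116) and AY761184 from 2280 ± 1064 to 10596 ± 5803 (log2 fold change 2.22, SE 0.58, edgeR adjusted p = 0.0129), and both calls ended without Lgr5-EGFP replicate 1. Over the list alone 12 rose and 2 fell. Of 16 goblet genes 4 rose, namely Fcgbp (log2 fold change 2.92, SE 0.64, edgeR adjusted p = 0.00439), Tff3 (1.86, SE 0.44, edgeR adjusted p = 0.00702) and, named after their values were seen, Zg16 and Clca3; for the list alone the count was 5. Fcgbp and Tff3 lost their calls without Lgr5-EGFP replicate 2. Of 7 hormones 2 rose: Sst (somatostatin) and Gip had no count in the Lgr5-EGFP plates and were at least 193-fold and 239.9-fold higher, but their levels in single YFP plates ran from 1.43 to 749 and from 0 to 949 CPM. Both calls ended when either Lgr5-EGFP plate was left out, and that on Sst also without YFP replicate 3. Of 10 enteroendocrine genes 2 rose, Ddc (log2 fold change 1.61, SE 0.20, edgeR adjusted p = 8.46e-05) and Neurog3, named after its values were seen. In whole organoid replicate 1, Ddc outside the enteroendocrine-like wells stood at 18.9% of its level inside them. The median over 19 such genes was 1.16%, so the rise of Ddc alone does not point to enteroendocrine cells. For the enteroendocrine and hormone lists alone the counts were again 2 each. Camera called the Paneth and enteroendocrine lists with a preset correlation (adjusted p = 0.0107 and 0.0139) and not with an estimated one (adjusted p = 0.575 and 0.491 with an estimated correlation), and did not call the goblet (adjusted p = 0.110) or hormone (adjusted p = 0.352) lists. The Paneth and enteroendocrine lists and Ddc lost their calls with each well thinned to 1500 counts, and the lists also without Lgr5-EGFP replicate 1, where the hormone list was called lower. The goblet list was called higher with thinned wells, without a filter on low counts, with whole barcode numbers, without Lgr5-EGFP replicate 1 and without YFP replicate 4.

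Of 18 immediate early and heat shock genes, which cell isolation is known to induce, 10 rose in YFP plates and 1, Hsp90aa1, fell by 0.59 on the log2 scale (SE 0.16), and Fos rose from 190.4 ± 9.30 to 287 ± 51.7 CPM (log2 fold change 0.58, SE 0.19, edgeR adjusted p = 0.0341). The counts over the list alone were again 10 and 1. Camera, but not with wells thinned to 1500 counts, called this list with a preset correlation (adjusted p = 0.00628) and not with an estimated one (adjusted p = 0.310 with an estimated correlation). Of 20 cell cycle genes 6 rose and 4 fell, with the same counts over the list alone: Ube2c rose by log2 0.79 (SE 0.18) and Mki67 by log2 0.54 (SE 0.19), while Top2a fell by 0.60 (SE 0.19) on the log2 scale. The calls on Fos, Hsp90aa1, Ube2c, Mki67 and Top2a ended without Lgr5-EGFP replicate 1. Those on Fos, Mki67 and Top2a also ended without Lgr5-EGFP replicate 2, on Fos without YFP replicate 2 or 3, on Mki67 without YFP replicate 1, 2 or 5 and on Top2a without YFP replicate 1. With each well thinned to 1500 counts Mki67 had a log2 fold change of -0.31. Camera did not call the cell cycle list (adjusted p = 0.832) or the tuft list (adjusted p = 0.832), whose median and mean lay above 0 beside a negative test direction and of whose 8 members none changed. Of the immune list 1 gene passed the filter, Lyz2, and it rose from 1.12 ± 0.306 to 30.3 ± 36.4 CPM (edgeR adjusted p = 0.0137), a call that ended when either Lgr5-EGFP plate was left out. The stromal, fibroblast and embryonic stem cell lists had fewer than 3 members past the filter.

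Outside the lists, Retnlb fell from 142 counts over the Lgr5-EGFP plates to 2 over the YFP plates, a ratio of 76.8 with a counting interval of 20.9 to 640.4. Bex1 fell from 94.6 ± 15.1 to 2.93 ± 2.62 CPM (log2 fold change -4.82, SE 0.33, edgeR adjusted p = 2.89e-06), Cd177 by 4.10 (SE 0.38) and Dusp22 by 4.10 (SE 0.32) on the log2 scale. In 1 fit over all 5 groups the calls on Lgr5, Tff3, Defa24, AY761184, Gm15284, Gip, Hes6, Fos, Hsp90aa1, Ube2c, Mki67 and Top2a ended. The number of called genes was 581 with each well thinned to 1500 counts. It was 1199 without Lgr5-EGFP replicate 1 and 1104 without replicate 2.

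**Figure D3:**
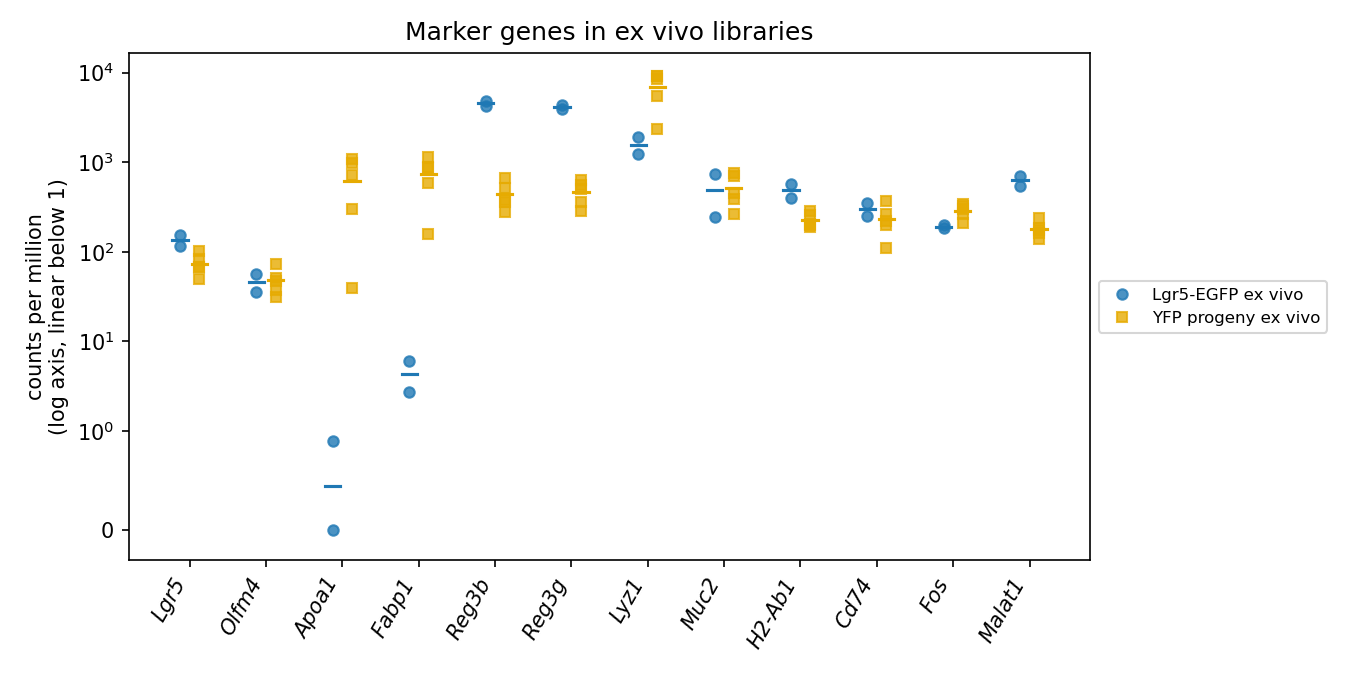
Level in CPM (vertical axis, logarithmic above 1 and linear below) of marker genes in ex vivo libraries; each symbol is 1 plate and each dash a group mean. Reg3b stood at 4807 and 4243 in the Lgr5-EGFP plates and between 278 and 659 in the YFP plates, and Malat1 separated the groups in the same direction.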

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

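Of the tests given here, those of carry-over, of the depth of whole organoid replicate 1 and of the depth of the Reg4-positive wells were chosen after the result was seen. The share of wells without those above 100000 counts was tested with an exclusion also chosen after seeing the data.

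Among 75 series of 5 YFP plates, 6 had a lone plate far from the rest. At 1 in 20, 3.75 would be expected by chance if the values were normally distributed. For skewed levels near 0 that number does not hold, so no excess is read from the 6. The gap of that plate to its neighbour, as a part of the whole range, was 1 for Retnlb (0 to 3.53 CPM), 0.734 for Ghrl (1.43 to 1100 CPM), 0.756 for Rgs13 (0 to 35.3 CPM), 0.737 for Dclk1 (0 to 59.9 CPM), 0.773 for Atoh1 (0 to 34.2 CPM) and 0.828 for Lyz2 (6.95 to 94.1 CPM).

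Signal also appeared in data that entered no comparison. Of the 2 tables matched to no library entry, the first held 1380 counts of embryonic stem cell genes and 5010 of fibroblast genes. It held more of enterocyte (24617), Paneth (6656) and goblet (5013) genes. At least 1% of counts fell on embryonic stem cell genes in 5 of its 96 wells, on fibroblast genes in 7 and on enterocyte genes in 55. The second table held 24805 counts of enteroendocrine and 40704 of Paneth genes. The dsRed reporter was counted in 31 of 75 wells (41.3%) of Reg4-positive replicate 1.

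In whole organoid replicate 1 enteroendocrine transcripts were found in most wells: Chgb was counted in 77.2% of wells against 1.44% in replicate 2. Greater depth was argued against, since after thinning 42.8% of replicate 1 wells held Chgb against 0.957%. Carry-over of Reg4-positive libraries as the main source was argued against as well, since the Lyz1 to Chgb ratio was 0.0247 of the lower Reg4-positive one. That ratio took all wells, and 3464 of 4773 Chgb counts lay in the 21 enteroendocrine-like wells. The other wells held 1309 Chgb counts, beside at most the 61 Lyz1 counts of the whole replicate. The lower Reg4-positive ratio was 0.517. Carry-over as a smaller part of these counts was not excluded. Spread of RNA from enteroendocrine cells of the same plates may contribute and stays open: over 19 genes the level outside against inside the enteroendocrine-like wells had a median of 1.16% and an upper quartile 2.38 times the lower, between the bounds set beforehand. A biological difference between the passages was not tested. Markers counted beyond their class were not particular to this library. In Reg4-positive replicate 2, Chgb was counted in 98.8% and Lyz1 in 95.1% of wells (88.9% and 71.6% after thinning). There 60.5% of wells were enteroendocrine-like and 19.8% Paneth-like. In Reg4-positive replicate 1, Lyz1 was counted in 86.7% of wells, while 13.3% were Paneth-like and 65.3% lay in the cluster with goblet and Paneth markers. In YFP replicate 5, Chgb was counted in 51.5% of wells, while 4.41% were enteroendocrine-like. Over the YFP plates, Fabp1 was counted in 48.6% to 92.5% of wells, while 5.71% to 17.5% were enterocyte-like. The cause in the Reg4-positive and YFP libraries was not tested.

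The Reg4-positive replicates held different cell classes, with enteroendocrine-like shares of 9.33% and 60.5%. Different depth of the wells was argued against, since the thinned shares still lay 52.4 percentage points apart. The gap without the wells of very high counts was 53.5 points, but leaving out 3 of 81 wells could not have brought it below 49.6 points, so this says nothing about them. A different sorting gate or a difference between the passages may account for the gap, and neither was tested.

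The many genes changed between YFP and Lgr5-EGFP plates may reflect a difference that all cell classes of a library share, or a different mix of classes. Within goblet-like and Paneth-like wells (49 YFP, 15 Lgr5-EGFP) the log2 ratio of 1234 called genes outside the lists was 0.531 of that over all wells in the median (bootstrap interval 0.319 to 0.849), and 78.3% had the same direction. The interval lay above the lower bound, below which a mix of classes as the whole cause was to be seen. The median lay above the upper bound, beyond which that was to be excluded, but the interval held this bound. The bounds had been written for the median alone, and the interval resampled wells, not plates. With the upper bound inside the interval, nothing is concluded from the test about either cause. A shared difference and a part played by the mix cannot be told apart, with 15 wells in the smaller set. Descent from labelled stem cells, which the design names, also stays open.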

How the results depend on the processing

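Of the alternatives given here, wells above 100000 counts left out, whole barcode numbers and the first naming rule were chosen after seeing the data. Over the settings run, results on single genes stayed on the same side of the threshold in 2839 cases, came to pass in 165 and no longer passed in 108, and in 4 a change that passed in either fit turned. For gene lists, by the direction given by camera, these numbers were 451, 22, 11 and 3. The cases counted as the same include results that passed in neither fit and changed sign. Of the values that answer a comparison, 18 moved by more than the limit set for a change and 96 by less, and except where stated the cause was not tested. For shares that limit was 1 SD between replicates, which is wide for the enteroendocrine-like share.

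For Reg4-positive against whole organoid the count of called genes was 1716 without a filter on low counts, 1910 in 1 fit over all 5 groups and 1128 with plates as units, and 209 to 933 with 1 library left out (lowest without Reg4-positive replicate 1). For Lgr5-positive organoid it was 1372 without the filter, 203 with wells thinned to 1500 counts, 1738 in the joint fit, 247 with plates as units and 143 without wells above 100000 counts, and 380 to 931 with 1 library left out (highest without Reg4-positive replicate 2). For YFP against Lgr5-EGFP it was 581 with thinned wells, which hold fewer counts, and 1104 to 2446 with 1 plate left out (lowest without Lgr5-EGFP replicate 2). Camera called 7 to 9, 6 to 9 and 7 lists with 1 library left out, and 4 lists in YFP plates with thinned wells. The enterocyte-like share was 5.26 percentage points with thinned wells and 5.18 to 12.1 with 1 plate left out (lowest without YFP replicate 5). The enteroendocrine-like share difference ran from 4.81 to 56.0.

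The cell cycle list in Reg4-positive libraries had a median log2 fold change of -0.71 without wells above 100000 counts. In the Lgr5-positive comparison the goblet list ran from -1.17 without whole organoid replicate 1 to 0.66 without replicate 2, Chga from -4.94 without whole organoid replicate 2 to 6.82 without replicate 1, and Chgb from -4.41 to 5.39 likewise. Without a filter on low counts, among others, Reg4, Lgr5, Lyz1, Chga, Chgb, Tac1, Spink4, Tff3 and Fabp1 passed in the Reg4-positive comparison, and Lgr5, Reg4, Chga, Chgb, Clca4, Smoc2 and Top2a in the Lgr5-positive one. This setting could shrink p-values at nearly the same fold change. Ghrl in YFP plates had a log2 fold change of 1.97 with the filter (edgeR adjusted p = 0.403). Without it the value was 1.94 (edgeR adjusted p = 1.20e-19). Passes without the filter are therefore weak support. In the joint fit, among others, Lgr5, Lyz1, Spink4, Tff3 and Fabp1, and Lgr5, Clca4, Smoc2, Slc12a2 and Top2a passed, respectively, and with plates as units Chga, Tac1, Spink4 and Tff3 were among those that passed in the Reg4-positive comparison. Plates of 1 passage are not independent replicates, so passes with plates as units are weak support. Without wells 49 to 96 of plate IV of whole organoid replicate 2, 603 and 384 genes were called. In YFP plates the gut hormones list had a median of 1.28 without Lgr5-EGFP replicate 1, although camera then called it lower, and ran up to 7.74 without replicate 2, and Mki67 stood at -0.31 with thinned wells.

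Replicate numbers do not pair the samples, since organoid groups came from different mice and only 2 numbers were shared. Same-numbered libraries had correlations of deviations of -0.103 in organoids and 0.0283 and -0.0624 ex vivo. With the replicate block 418, 259 and 2322 genes were called in the Reg4, Lgr5 and YFP comparisons, and camera called 8, 7 and 8 lists. Ghrl in YFP plates was then called lower, with a log2 fold change of -4.90 (edgeR adjusted p = 7.44e-06), where without the block it stood at 1.97 and did not pass (edgeR adjusted p = 0.403). With the block camera also called the YFP gut hormones list (adjusted p = 0.0205) and the goblet list higher, and no longer called the secretory progenitor list.

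The planned comparison of pool-and-split wells and the control library gave no value, because no table could be matched to either from its name. Wells 49 to 96 of YFP replicate 4 are not in the table used here, so keeping them was not run. At the depths, spread and replicate numbers of these libraries, 2-fold changes were recovered at 5.22%, 2.99% and 65.9% in the simulated Reg4, Lgr5 and YFP comparisons. These rates leave out genes of the lowest counts, on which no change was simulated. Whether depth, spread or replicate number limits the recovery was not tested.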

Other observations

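Within the enteroendocrine-like wells of organoids, a cluster of 15 wells was led by Afp, Reg4, Alb, Chga and Rgs2, and 12 of its wells came from Reg4-positive replicate 2. Afp and Alb, which encode the serum proteins alpha-fetoprotein and albumin, were named after their values were seen. In whole organoid, a cluster of 18 wells was led by Klf6, Areg and Hbegf, with Fos and Jun among its 10 leading genes, and 14 of these wells came from replicate 2. Another cluster of 47 wells, led by Rn45s, Tm6sf2 and Khk, held wells of whole organoid replicate 2 only. These clusters of 18 and 47 wells were left unnamed but had 9 and 6 enterocyte markers raised, respectively.

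Secretory classes made up small shares of the ex vivo plates. Goblet-like wells were 5.33% and 4.76% of the Lgr5-EGFP plates and 2.86% to 10.3% of the YFP plates. Paneth-like wells were 2.67% and 5.95% against 1.25% to 10.8%, and enteroendocrine-like wells 0% and 4.76% against 2.86% to 5.13%. The tuft-like cluster held 8 wells in all. These shares were not tested.

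The 2 tables matched to no library entry differed in how even their wells were. In the first, well totals ran from 1 to 75924 counts, and enterocyte genes took 1.61% of the counts of the median well and up to 13.3%. In the second, totals ran from 85 to 15851, and the median well held 4.42% enteroendocrine, 7.14% Paneth, 1.65% goblet and 1.18% gut hormone counts, with at least 1% of enteroendocrine and of Paneth counts in each of 96 wells.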
